A study of Mus musculus with 2 samples.

How the data were processed

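RNA with poly(A) tails was sequenced from activated regulatory T cells of a male mouse. The labels give 2 libraries, technical replicates 1 and 2 of biological replicate 1, with fragments of 100 to 300 bases made by acoustic shearing. The 2 libraries form 1 group. The means and SDs in the text are over these 2 libraries, and no p-value refers to animals. How the cells were sorted or activated is not given in the sources used here.

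For each library the authors deposited a gene table and a transcript table quantified on mm10 with GENCODE release M21, per the file listing deposited with each sample. The quantification tool and its version are not given in the sources used here. The expected count, an estimate of reads per gene or transcript that need not be whole, was deposited in both tables per the file headers. The deposited TPM scales these estimates by effective length to a fixed sum over all rows, and the deposited FPKM scales them by effective length and by the number of reads. The deposited isoform percent gives each transcript's share of its gene's TPM. A further deposited table gives a whole-number count per gene on mm10 with GENCODE release M4, and its counter and filters are not given in the sources used here. Length minus effective length in the gene table corresponds to reads of 50 bases.

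Gene symbols, types, coordinates (1-based), coding lengths and GC content came from GENCODE M21, which holds all 55536 gene identifiers. Of 22457 identifiers in the whole-number table, 22195 matched. Rows that name no gene were left out of library sizes and tests. They held 0.126% (phiX174) and 0.0167% (numbered rows of tRNA length) of reads in library 1 and 0.172% and 0.0140% in library 2, and the 96 ERCC spike-in rows held 0. The remaining estimated gene reads were 15076048 and 14635787 after rounding each gene to a whole number. TPM was used as deposited, so it includes those rows. For a gene with no reads the limit given is the TPM of 3 reads, which like all counting limits covers counting error only. Strandedness is not given in the sources used here, so genes overlapping on opposite strands are uncertain.

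The lists of genes and cell type markers, the tests and the alternatives were fixed before the data were examined, except where said. The 29 lists hold 315 genes, 15 of them in more than 1 list. They cover regulatory T cell core, activated regulatory T cell, resting T cell, T cell identity, helper regulators, cytokines, chemokine and cytokine receptors, transcription factors, cell cycle, T cell receptor response, immediate early and heat shock, interferon, glycolysis, apoptosis, housekeeping, sex-chromosome genes and 11 other cell types. Any list member could be named, with at least the 3 highest and the lowest of each list, except a few genes that are not reported here. The 20 genes of highest TPM were also named, and the 5 genes in each direction with the largest ratio between libraries among those past the threshold with 100 reads or more. Among list genes only Aldoa has 2 identifiers, and the one with reads was used. Genes counted as expressed at 1 TPM or more in both libraries. A list's level was its median log2(TPM + 1), described by its percentile among 10000 random lists of the same size from 22028 protein-coding genes.

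Expected counts were rounded to whole numbers, and each gene with a summed count of 10 or more was tested by an exact two-sided binomial test, 2 times the smaller tail, against library 2's 49.3% share of all gene reads. P-values were adjusted by Benjamini-Hochberg at 0.05. Log2 ratios add 0.5 to each library's count. edgeR 4.0.16 gave the common dispersion, TMM sizes and an exact test at a dispersion of 0.01, and DESeq2 1.42.0 gave size factors (R 4.3.3). Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

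The binomial test was tested on simulated Poisson libraries with 200 changed genes. Where these were raised and lowered in equal numbers, over 17336 genes it called 34% of 1.25-fold, 58% of 1.5-fold, 56% of 2-fold and 86% of 4-fold changes, and 6 of 17143 unchanged genes. Where all 200 were raised in library 2, over 17366 genes, the total of library 2 moved and 29 of 17167 unchanged genes were called beside 121 changed ones, more than the nominal rate. TMM and DESeq2 scaling were run as alternatives. The bound on B cell genes relative to Ighm was first applied to Cd79a, Igkc and Ms4a1, where the highest reached 3.52%, and then to all 7 other members of the list. Their median was tried as the test in its place after the values were seen, and is given as a description only. A coefficient of variation of 0.1 put into simulated libraries came back from edgeR as 0.0990 over 17371 genes.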

Results

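Polyadenylated RNA was sequenced from activated regulatory T cells, the Foxp3-expressing CD4 T cells that restrain immune responses. The cells came from a male mouse aged 4 months that carried a tamoxifen-inducible Cre at Foxp3 and a yellow fluorescent reporter at Rosa26. The labels name a haematopoietic cell of the bone marrow as their origin and give no tissue of isolation. Both libraries were labelled as technical replicates, 1 and 2, of biological replicate 1. There was therefore 1 group and no second condition, and the question the data can answer is which genes these cells expressed and at what level. Values below are the mean ± SD of the 2 libraries (n = 2 technical libraries of 1 biological sample). Each SD covers differences between technical replicates, counting error included, and not the spread between animals. From 2 values an SD can fall below the counting error by coincidence, so a small SD does not bound that error. Counts of list members above or under a level use that mean. Library 1 held 15076048 estimated gene reads and library 2 held 14635787. Protein-coding genes took 89.8% of them in library 1 and 90.8% in library 2.

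A total of 13251 of 55536 genes reached 1 TPM, a length-scaled measure of transcript abundance, in both libraries, and 10171 of these were protein-coding. Of the protein-coding genes, 6497 reached 10 TPM, 1157 reached 100 TPM and 109 reached 1000 TPM in both. A further 2203 genes reached 1 TPM in 1 library only. The most abundant gene was Actb, which encodes beta-actin, at 41775 ± 1179 TPM. Cytoskeletal Tmsb4x (11308 ± 526 TPM), translation factor Eef1a1 (8054 ± 51.2 TPM) and class I antigen-presentation subunit B2m (6655 ± 185 TPM) were also among the 20 highest. Ribosomal protein genes filled other places, among them Rps19, Rpl32, Rpl13a, Rpl41, Rps27, Rps14 and Rps18, led by Rps19 at 8531 ± 96.0 TPM. Mitochondrial mt-Co3, mt-Atp6, mt-Atp8, mt-Rnr2 and mt-Ts1 and the nuclear noncoding RNA Malat1 (4837 ± 141 TPM) were in the same group. The ribosomal RNA gene CT010467.1 (11632 ± 1522 TPM) and AY036118 (6726 ± 1123 TPM), annotated as a lincRNA, overlap on chromosome 17, so the split of reads between them is uncertain. Genes annotated as rRNA took 1.88% of gene reads in library 1 and 1.52% in library 2, which leaves out AY036118 and the mitochondrial rRNA genes, the latter at 1.09% and 1.03%. All 10 housekeeping genes were expressed, from Actb, Eef1a1 and B2m down to Tbp at 39.8 ± 5.13 TPM. The 4 Y-linked genes were expressed, with Eif2s3y at 131 ± 4.55, Ddx3y at 78.6 ± 2.49, Uty at 45.5 ± 1.53 and Kdm5d at 20.3 ± 1.71 TPM. Xist, the RNA that silences an X chromosome in females, was at 0.27 ± 0.071 TPM.

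All 16 members of the regulatory T cell core list were expressed above 10 TPM, and 10 of them above 100 TPM. Izumo1r, the folate receptor FR4, was highest at 797 ± 88.2 TPM. The costimulatory receptors Tnfrsf4 (OX40) and Tnfrsf18 (GITR) followed at 614 ± 10.1 and 580 ± 4.07 TPM. Actin-capping Capg was at 505 ± 77.8 TPM, and the transcription factor Ikzf2 (Helios) at 468 ± 3.02 TPM. The interleukin-2 receptor chains Il2rb and Il2ra reached 426 ± 79.4 and 239 ± 4.31 TPM, and the inhibitory receptor Ctla4 reached 232 ± 23.9 TPM. Nrp1 (169 ± 14.6 TPM) and the adenosine-producing enzyme Nt5e (135 ± 11.4 TPM) were next, and its partner Entpd1 was at 40.5 ± 1.98 TPM. Foxp3, the transcription factor that defines the lineage, was the lowest member at 22.4 ± 2.06 TPM, from 445 and 396 estimated reads. Ikzf2 was 21 ± 1.8 times and Il2ra 10.7 ± 1.18 times as abundant as Foxp3 by TPM. The TPM of Foxp3 and Ikzf2, and so these ratios and the place of Foxp3 in the list, depend on the lengths of the transcripts to which the model assigned the reads, which are uncertain for both genes (see the transcript shares below). The list's median log2(TPM + 1) was 7.62 ± 0.12, above that of all 10000 random lists of 16 protein-coding genes. On mm10, Foxp3 (ENSMUSG00000039521.13) lies on chromosome X from 7573644 to 7595245. Il2ra (ENSMUSG00000026770.5) lies on chromosome 2 from 11642807 to 11693193, Ctla4 (ENSMUSG00000026011.13) on chromosome 1 from 60887000 to 60915832 and Ikzf2 (ENSMUSG00000025997.13) on chromosome 1 from 69531214 to 69687245.

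**Figure D1:**
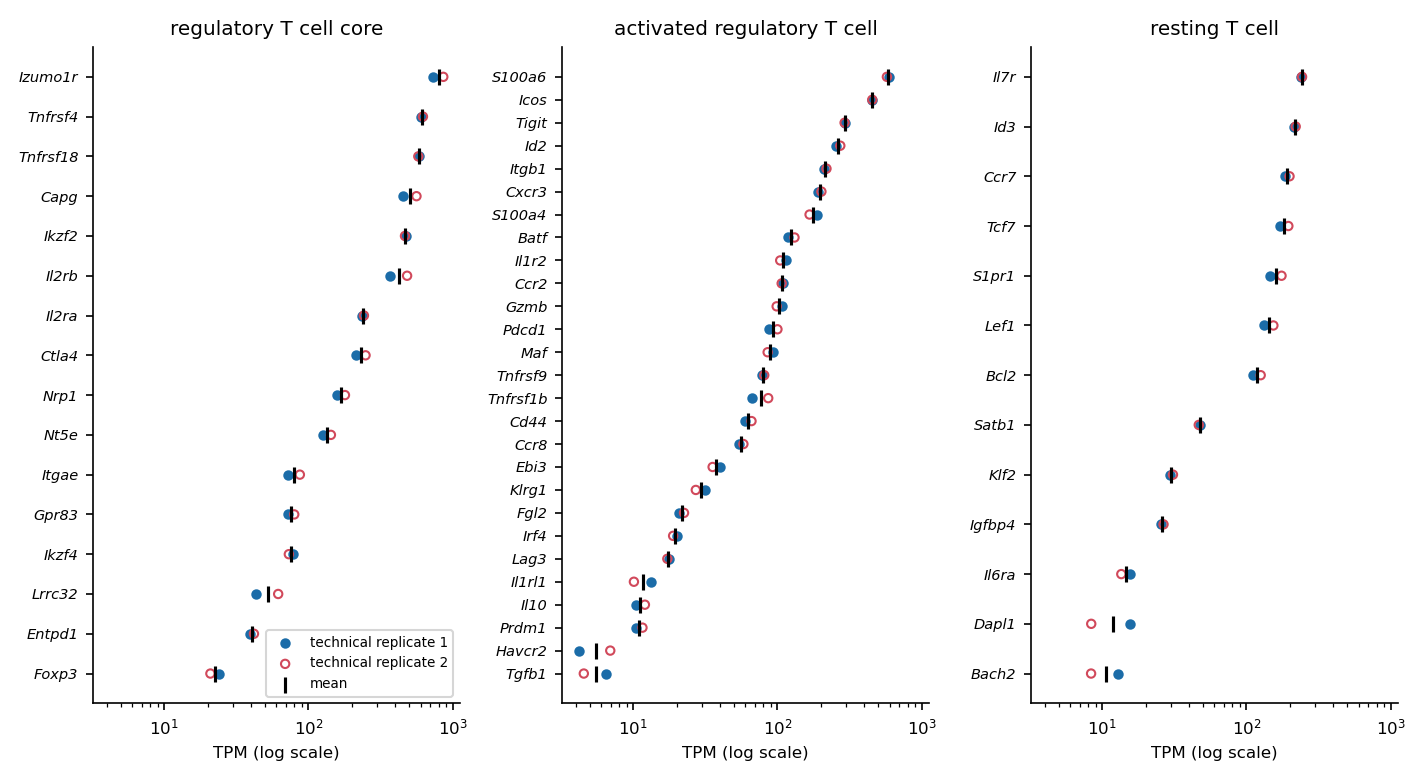
TPM (log axis) of members of the regulatory T cell core, activated regulatory T cell and resting T cell lists. Filled circles are technical replicate 1, open circles technical replicate 2 and bars their mean. Every gene drawn was detected in both libraries, with Foxp3 lowest in the core list at a mean of 22.4 TPM and Bach2 lowest in the resting list at a mean of 10.7 TPM.

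Genes of general T cell identity were all above 10 TPM, with 16 of 17 above 100 TPM. The T cell receptor constant regions Trbc2 (3387 ± 40.5 TPM), Trac (2745 ± 22.5 TPM) and Trbc1 (1834 ± 33.5 TPM) were highest. Estimated reads of Trbc1 and Trbc2 were not whole (13980.45 and 26781.55 in library 1), so the split of reads is uncertain for both. Cd2 was at 1199 ± 55.3, Cd3g at 1100 ± 26.8, the proximal kinase Lck at 1073 ± 126 and Cd4 at 212 ± 43.8 TPM. The list's median exceeded that of all 10000 random lists.

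All 27 members of the activated regulatory T cell list were above 1 TPM, 25 were above 10 TPM and 11 were above 100 TPM. The calcium-binding S100a6 was highest at 583 ± 14.5 TPM, followed by the costimulatory receptor Icos at 452 ± 2.72 TPM and the inhibitory receptor Tigit at 293 ± 2.02 TPM. The transcriptional regulators Id2 (262 ± 14.1 TPM), Batf (125 ± 9.43 TPM) and Maf (89.1 ± 5.09 TPM) were expressed, as were Cxcr3 (195.8 ± 8.08 TPM), the decoy interleukin-1 receptor Il1r2 (110 ± 7.35 TPM) and granzyme B, Gzmb (103 ± 6.02 TPM). Pdcd1, which encodes PD-1, was at 93.7 ± 8.77 TPM. Klrg1 was at 29.3 ± 3.01, the repressor Prdm1 (Blimp-1) at 11 ± 0.79 and the cytokine Il10 at 11.2 ± 1.16 TPM. Tgfb1 was the lowest at 5.53 ± 1.39 TPM, close to Havcr2 at 5.57 ± 1.94 TPM.

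The resting T cell list was expressed in the same libraries. Each library gives 1 level per gene over all its cells, so whether the same cells expressed both lists cannot be told. By mean TPM all 14 members were above 10 TPM and 8 above 100 TPM, and 12 were above 10 TPM in both libraries. The interleukin-7 receptor chain Il7r was at 241 ± 2.66 TPM and Id3 at 216 ± 4.85 TPM. The lymph node homing receptor Ccr7 was at 191 ± 10.5 TPM. The transcription factors Tcf7 and Lef1 were at 183 ± 16.4 and 143 ± 14.8 TPM, and the egress receptor S1pr1 was at 160 ± 21.1 TPM. Bach2 was lowest at 10.7 ± 3.25 TPM, near Dapl1 at 12.0 ± 5.05 TPM. The median log2(TPM + 1) was 6.37 ± 0.09 for the activated list and 7.03 ± 0.14 for the resting list, both above all 10000 random lists of their size. The activated list's median minus the resting list's was -0.63 in library 1 and -0.69 in library 2, a mean of -0.66 ± 0.05. This SD covers the libraries and not the choice of genes, and with list means in place of medians the difference was -0.26. Of the 27 activated genes, 7 exceeded the resting list's median of 130.5 TPM. The 2 lists hold different genes, and no resting cells were measured, so these values describe levels within the sample and give no change upon activation.

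Among regulators of helper T cell lineages, Gata3 (type 2) was highest at 97.4 ± 9.90 TPM and Rora followed at 47.2 ± 0.601 TPM. Tbx21 (type 1) and the follicular regulator Bcl6 were low, at 3.54 ± 0.240 and 3.38 ± 0.163 TPM. Gata3 was 27.5 ± 0.930 times as abundant as Tbx21. Eomes was lowest at 0.20 ± 0.18 TPM. Effector cytokine genes were scarce. Of 13, 9 were under 1 TPM and Tnf alone exceeded 10 TPM, at 15 ± 1.7 TPM. Ifng was at 6.89 ± 0.262 and Il4 at 5.14 ± 2.19 TPM. Il9, Il13, Il17a, Il22 and Il3 had no reads in either library, for which 3 reads would have given at most 0.526, 0.222, 0.228, 0.242 and 0.442 TPM. The helper list's median stood at the 75.4th percentile of random lists and the cytokine list's at the 28.2nd. Against random lists of expressed genes alone these fell to 1.54 and 0. With the mean of log2(TPM + 0.1) the percentiles were 91.5 and 5.56, and they were 86.0 and 13.6 in the whole-number table.

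Of 17 chemokine receptors, 13 were above 1 TPM and 3 above 100 TPM. Cxcr3 was highest, then Ccr7 and Ccr2, the last at 108 ± 1.22 TPM. Cxcr6 (92.7 ± 6.0 TPM), Ccr6 (74.3 ± 7.88 TPM), Ccr8 (56.2 ± 2.57 TPM), the follicle-homing Cxcr5 (40.0 ± 3.95 TPM) and Ccr4 (31.2 ± 1.58 TPM) were also expressed. Ccr7 was 3.4 ± 0.032 times as abundant as Ccr8. Cxcr1 and Cxcr2 had no reads, which allows up to 0.207 and 0.0992 TPM. The median was at the 97.8th percentile of random lists, and at the 26.0th among expressed genes. Of 26 cytokine receptor genes, 25 were above 1 TPM and 7 above 100 TPM. The common gamma chain Il2rg led at 1162 ± 136 TPM, followed by Il2rb and by Ifngr1 at 334 ± 5.34 TPM. Il27ra was at 150 ± 14.5 and Il18r1 at 78.7 ± 3.20 TPM. The interleukin-33 receptor Il1rl1 (ST2) was at 11.8 ± 2.31 TPM, and Il1r1 was lowest at 0.30 ± 0.071 TPM.

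All 20 listed Foxp3 partners and T cell transcription factors were expressed. Ets1 stood out at 600 ± 74.4 TPM, followed by Foxp1 at 157 ± 3.02 and Ikzf1 (Ikaros) at 103 ± 4.19 TPM. Runx1 was at 26.8 ± 2.0 and Stat5b at 24.2 ± 4.60 TPM. Foxo3 was lowest at 7.31 ± 0.325 TPM. Cell cycle genes were expressed above 1 TPM in 22 of 23 cases and above 10 TPM in 18. Hmgb2 (352 ± 16.1 TPM), Stmn1 (197 ± 1.93 TPM), the replication clamp Pcna (139 ± 1.48 TPM) and the nucleotide synthesis gene Rrm2 (105 ± 4.65 TPM) led. Top2a was at 91.3 ± 3.15, Birc5 at 63.1 ± 5.13 and Mki67 at 17.0 ± 0.799 TPM, and E2f1 was lowest at 0.995 ± 0.431 TPM.

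The T cell receptor response list had all 14 members above 1 TPM. Nfkbia, the inhibitor of NF-kappaB, was at 392 ± 6.46 TPM, Cd5 at 336 ± 40.6 and the early activation marker Cd69 at 187 ± 2.67 TPM. Myc (79.2 ± 11.9 TPM), Egr2 (39.6 ± 10.8 TPM) and Nr4a1 (32.8 ± 6.19 TPM) were expressed, while Nr4a3 and Nr4a2 were at 1.54 ± 0.0566 and 1.28 ± 0.0141 TPM. In the immediate early and heat shock list 11 of 15 genes were above 1 TPM and 8 above 10 TPM. The chaperone Hspa8 (2613 ± 135 TPM), Btg2 (144 ± 18.0 TPM) and Zfp36 (90.5 ± 13.8 TPM) were highest. Fos and Jun were low, at 6.24 ± 1.68 and 5.67 ± 0.325 TPM. Ier2 (39.6 ± 2.40 TPM) and Junb (22.02 ± 1.44 TPM) were higher. Fosb (0.53 ± 0.099 TPM) and Atf3 (0.135 ± 0.0636 TPM) were lower, and the heat-inducible Hspa1b was lowest at 0.020 ± 0.028 TPM. The list's median was at the 98.5th percentile of random lists, and at the 38.5th among expressed genes. Such genes can rise during cell handling, which was not tested, since no unhandled cells were measured.

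All 14 interferon response genes were above 1 TPM and 12 above 10 TPM. Ifi27l2a was at 1235 ± 55.7 and Gbp4 at 153 ± 2.67 TPM, with Rsad2 lowest at 3.25 ± 1.70 TPM. All 15 glycolysis genes were expressed. Ldha (805 ± 31.2 TPM), Pkm (619 ± 134 TPM) and Aldoa (584 ± 44.0 TPM) were highest, and Gapdh was at 217 ± 13.7 TPM. The hexokinase Hk2 was lowest at 3.52 ± 0.417 TPM, against 46.1 ± 8.77 TPM for Hk1. All 14 apoptosis regulators were above 1 TPM. The pro-survival Bcl2a1b, which shares reads with near-identical family copies and is uncertain, was at 203 ± 1.61 TPM. Casp8 was at 137 ± 1.31, Cflar at 128 ± 3.27 and Bcl2 at 118 ± 10.7 TPM, and pro-apoptotic Bcl2l11 (Bim) and Bbc3 (Puma) were at 12.7 ± 1.58 and 1.01 ± 0.127 TPM.

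Markers of other cell types were mostly near zero. Of 64 markers in 11 lists, 39 were under 1 TPM. Their summed TPM was 6.96% ± 0.132 of that of the T cell identity list, and 4 genes made up most of it. These were the immunoglobulin heavy chain constant gene Ighm (719 ± 57.6 TPM), the protease inhibitor Cst3 (122 ± 5.73 TPM), the adhesion molecule Pecam1 (78.1 ± 1.2 TPM) and Cd79b (38.5 ± 3.15 TPM). Without them, a choice made after seeing the values, the remaining 60 markers summed to 0.688% ± 0.0029. The B cell list came to 5.15% ± 0.190, although Pax5 was at 0.040 ± 0.057, Ms4a1 at 0.53 ± 0.198, Cd79a at 1.48 ± 0.311 and the light chain constant gene Igkc at 23.3 ± 0.870 TPM. Ighm (ENSMUSG00000076617.9) lies on chromosome 12 from 113418558 to 113422730.

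Cytotoxic T cell markers came to 0.0881% ± 0.0162, with Cd8b1 at 12.4 ± 3.44 and Cd8a at 1.11 ± 0.453 TPM. Gamma delta T cell markers came to 0.162% ± 0.00977, with Tcrg-C1 at 17.0 ± 0.247, Tcrg-C2 at 3.35 ± 0.332, Tcrg-C4 at 2.79 ± 1.87 and Trdc at 1.55 ± 0.0212 TPM. The dendritic cell list, at 0.846% ± 0.0673, consisted mostly of Cst3, with H2-Aa at 3.52 ± 0.735 and Zbtb46 at 2.87 ± 0.552 TPM and no reads on Itgax. The stromal, endothelial and epithelial list, at 0.523% ± 0.0121, consisted mostly of Pecam1, with Epcam at 1.19 ± 0.460, Col1a1 at 0.26 ± 0.283 TPM and no reads on Cxcl12. Erythroid markers came to 0.133% ± 0.0146, with Hba-a2 at 6.80 ± 0.141, Hbb-bs at 5.51 ± 1.08 and Car2 at 2.54 ± 0.806 TPM. Monocyte and macrophage markers came to 0.0355% ± 0.00625, with Cd68 at 2.53 ± 0.0566, Lyz2 at 1.72 ± 1.57, Itgam at 0.58 ± 0.184 TPM and no reads on Cd14. Natural killer cell markers came to 0.0123% ± 0.00194, with Klrb1c at 1.55 ± 0.629, Klrd1 at 0.345 ± 0.261 TPM and no reads on Ncr1. Plasma cell markers (0.00306% ± 0.00262), neutrophil markers (0.00182% ± 0.000857) and platelet and megakaryocyte markers (0.00344% ± 0.0000077) were all under 1 TPM. Jchain, Tnfrsf17, Sdc1, S100a8, Camp, Ngp, Pf4, Itga2b and Gp9 had between 0 and 11 reads per library, and Mzb1, S100a9 and Ppbp had none.

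**Figure D2:**
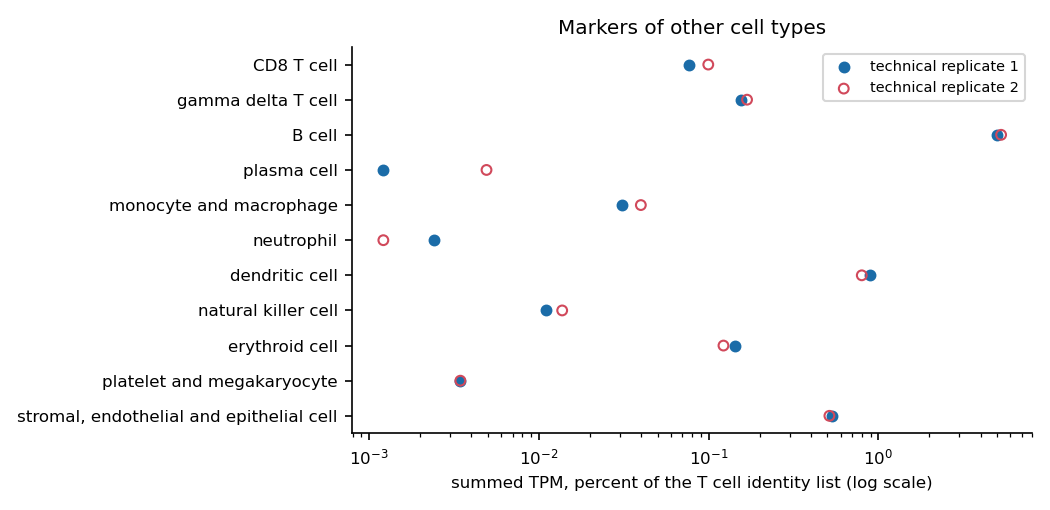
Summed TPM of each marker list as a percent of the summed TPM of the T cell identity list (log axis). Filled circles are technical replicate 1 and open circles technical replicate 2. The B cell list stands at 5.15% on average and every other list under 1%.

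Transcript shares were compared for 18 genes listed in advance. They are shares of the gene's TPM, which is scaled by length, and not of its reads. The most abundant transcript was the same in both libraries for 16 of them and was annotated as protein-coding in 13. Ctla4 was almost entirely Ctla4-201 (97.8% ± 1.61), as Tcf7 was Tcf7-201 (98.6% ± 0.488). Pkm-201 held 79.9% ± 1.63 of Pkm and Prdm1-201 held 79.5% ± 1.87 of Prdm1. The TPM of Icos was divided between Icos-202 (51.8% ± 0.976) and Icos-201 (48.2% ± 0.976). By estimated reads Icos-202 led, with 9342 in library 1 and 8657 in library 2, against 2017 and 1976 for Icos-201. For Ikzf2 most of the TPM went to Ikzf2-205, a retained-intron transcript, at 56.6% ± 0.417, ahead of the coding Ikzf2-201 at 30.3% ± 0.177. By estimated reads the order was reversed. The longer Ikzf2-201 had 16368 in library 1 and 15183 in library 2, against 6160 and 5701 for Ikzf2-205. For Foxp3 the model gave 82.0% ± 9.41 of the TPM to Foxp3-207, which is annotated for nonsense-mediated decay. The 4 Foxp3 transcripts of 3000 bases or more received 31.8 and 30.3 reads of 445 and 396. Il1rl1 and Foxp1 had different leading transcripts in the 2 libraries. In Il1rl1, Il1rl1-201 held 54.4% in library 1 and 28.0% in library 2. Across 7817 genes with several transcripts and 5 TPM or more, 87.2% had the same leading transcript in both libraries. Reads of 50 bases seldom span the features that separate transcripts, so these shares are model estimates.

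The 2 libraries were then compared with each other, which tests the libraries and not a biological condition. Pearson's r across 15454 genes was 0.968 and Spearman's rho was 0.960 (genes are not independent replicates). An exact two-sided binomial test with Benjamini-Hochberg adjustment found 4198 of 17271 genes to differ, 2189 higher in library 2 and 2009 higher in library 1. The direction of the majority depended on the scaling: 2348 and 1858 with TMM, but 2039 and 2194 with DESeq2 size factors. This test allows for counting error only. Among them, 67.7% differed by less than 1.5-fold, and 887 by 2-fold or more. In the core list 11 of 16 genes differed, and 12 did when adjusted over the list alone. Of the 11, 9 were higher in library 2, among them Il2rb (log2 ratio 0.27) and Lrrc32 (0.38). In the T cell identity list 12 of 17 differed (13 adjusted over the list alone), with Cd4 higher in library 2 at a log2 ratio of 0.43. In the glycolysis list 9 of 15 differed (9 adjusted over the list alone), all higher in library 2, with Pkm at 0.45. In the activated list 11 of 27 differed (11 adjusted over the list alone), and 8 of these were higher in library 1. In the resting list 7 of 14 differed (8 adjusted over the list alone). The housekeeping list had 7 of 10 differ (9 adjusted over the list alone), so a high share is not particular to T cell genes. Genes with more reads were called more often: 30.7% differed at a summed count of 50 or more, against 24.3% of all genes tested. Foxp3 did not pass the test, at a log2 ratio of -0.13 (exact binomial test, adjusted p = 0.416). edgeR's common dispersion was 0.0167, a coefficient of variation of 12.9% between the libraries. With a fixed dispersion of 0.01, edgeR's exact test called 496 genes in place of 4198, 212 higher in library 2 and 284 higher in library 1, and 0 in each of the core, identity, glycolysis, activated and resting lists. Among the other lists it called Bst2 and Rsad2 (interferon response), Bax (apoptosis regulators) and Lyz2 (monocyte and macrophage), all higher in library 2. The fixed 0.01 lies below the common dispersion of 0.0167 of these libraries, so this test still understates the spread between them.

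The ratio of library 2 to library 1 moved with base composition. Over 9677 protein-coding genes with 100 reads or more, the log2 ratio had a Spearman's rho of 0.236 with the GC content of the longest transcript. With these genes cut into 10 groups of rising GC content, the median log2 ratio was -0.07 in group 1, 0.09 in group 9 and 0.06 in group 10. Several of the genes with the largest ratios are pseudogenes, histone copies or antisense genes, which can share reads with other genes and are uncertain. Pseudogenes Gm8226 and Gm5537, histone gene Hist2h2aa2, Fam220a (ENSMUSG00000118332.1) and Chtf8 (ENSMUSG00000117748.1) led in library 2. For Fam220a and Chtf8 the ratio is that of the identifier given, which had no whole-number count. Whether these symbols have further identifiers was not checked. Gm8226 had 0.15 and 200 reads. Zfp781, pseudogene Rpl7a-ps11, Pls3, Mrpl23 and antisense gene Gm43126 led in library 1. Pls3, an actin-bundling gene, had 97 reads in library 1 and 13 in library 2 (exact binomial test, adjusted p = 1.32e-14), and 51 and 6 in the whole-number table. That table comes from the same libraries and is no independent check. The other named genes matched there had few counts: Mrpl23 had 11 and 6, Zfp781 1 and 0, and Hist2h2aa2 0 and 0. Their large ratios therefore rest on the estimated reads. Chtf8, with 13.2 and 110 estimated reads, was at 3.32 and 4.63 TPM, so its ratio depends on how reads were assigned.

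**Figure D3:**
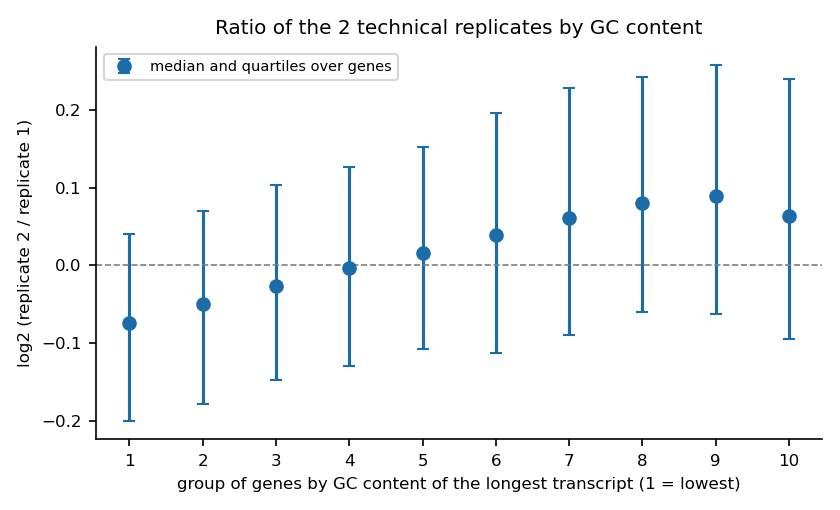
Log2 ratio of technical replicate 2 to technical replicate 1 for 9677 protein-coding genes, in 10 groups of rising GC content. Points are medians and bars quartiles over genes. The median goes from -0.07 in group 1 to 0.09 in group 9 and 0.06 in group 10.

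Each library also had a separate table of whole-number counts. It totalled 3478224 in library 1 and 3475360 in library 2, and ranked 22195 matched genes much as TPM did, with a Spearman's rho across genes of 0.923 in library 1 and 0.927 in library 2. Among genes of 1 TPM or more the mean was 0.774. The tables parted at high expression. Actb had 390739 estimated reads in library 1 and a whole-number count of 1991, and the leukocyte phosphatase Ptprc (CD45) had 43452 and 7120, the highest whole-number count. The median ratio of whole-number to estimated count was 0.443 in group 5 of 10 by reads per exonic base and 0.216 in group 10 of library 1, and 0.437 and 0.223 in library 2.

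**Figure D4:**
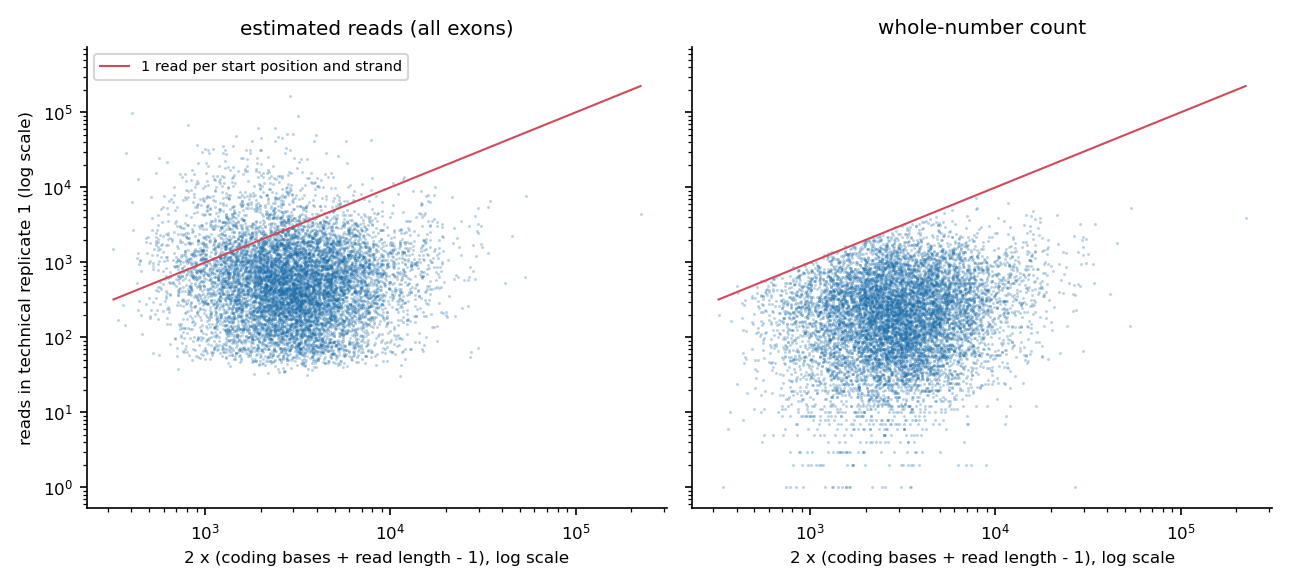
Reads of technical replicate 1 for 9480 protein-coding genes against 2 × (coding bases + read length - 1), both axes logarithmic. The left panel shows estimated reads and the right panel whole-number counts, and the line marks 1 read per start position and strand. Estimated reads exceed 1.2 times the line in 927 genes and whole-number counts in 0 of these.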

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

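Reads outside the genes were flagged because they exceed what a count of 0 allows and the comparisons above do not use them. The phiX174 row, a sequencing control genome, held 18975 reads in library 1 and 25253 in library 2. The numbered rows of tRNA length held 2522 reads in library 1 and 2057 in library 2, which through their short length made up 8411 and 7312 TPM. The 96 ERCC spike-in rows held 0 reads in both libraries. With 2 libraries in 1 group, no test of outlying samples or of differences between groups applied.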

How the results depend on the processing

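The count of genes expressed in both libraries stayed within 1.5 times of 13251 under the 7 alternatives, from 9184 at 5 TPM to 15077 at 0.5 TPM, and was 14274 to 14431 with 1 library left out. The percentile of the core, activated and resting lists was 100, the end of its scale, under all alternatives, so it says little about dependence on the processing. Over the other 25 lists, 43 of 150 alternatives moved the percentile by more than 5 points, 12 upward and 31 downward, and 16 of the latter used only expressed genes as background. The activated minus resting difference stayed negative, moved to -0.26 with means, and was -0.69 to -0.63 with 1 library left out. Other cell type markers, 6.96% as reported, were 10.3% with expected counts, 0.0398% with medians and 0.688% without Ighm, Cst3, Pecam1 and Cd79b, which was chosen after seeing the data, and 6.87% to 7.06% with 1 library left out. Between libraries 4198 of 17271 genes differed, and 496 of 17271 did with edgeR at a dispersion of 0.01. The whole-number table gave 1092 of 10978 genes, and the transcript level gave 17207 of 46979 transcripts. Whole-number counts level off at high expression, and transcript counts are model estimates whose error the test leaves out. Neither number is therefore a like check on the 4198. TMM gave 4206, DESeq2 size factors 4233, and a null share set within 10 groups of GC content, chosen after seeing the data, gave 3995. The correlation of the libraries, 0.968, was 0.901 with a pseudocount of 0.1, 0.986 without a filter, 0.960 by rank and 0.971 with FPKM. The share of genes with the same leading transcript, 87.2%, was 84.0% from 1 TPM, 90.9% from 20 TPM and 59.9% where that transcript also had to hold 50% or more. The rho between the gene tables, 0.925, was 0.774 among genes of 1 TPM or more and 0.923 to 0.927 with 1 library left out. The cause was not tested for these. No paired analysis was possible because there is 1 group. Genes under about 10 reads per library are limited by depth.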

Other observations

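Variable segments of the T cell receptor, which were not among the fixed lists and were chosen after seeing the data, were broadly used. Of 35 Trbv genes, 23 were above 1 TPM, with a summed TPM of 2810 ± 31.7 (SD, n = 2 technical libraries). Trbv13-2 took 11.7% ± 0.381 of it, Trbv3 9.62% ± 0.439, Trbv5 7.44% ± 0.247, Trbv13-1 6.52% ± 0.292, Trbv15 6.38% ± 0.0863 and Trbv13-3 6.06% ± 0.499. Of 128 Trav genes, 106 were above 1 TPM, summing to 1799 ± 24.0 TPM. The highest, Trav7d-2, took 4.76% ± 0.387 and Trav7-4 took 4.39% ± 0.183. Trav genes include recently duplicated copies, so the split among them is uncertain. Some Trbv genes also had estimated reads that were not whole, such as Trbv13-2 with 1223.67 in library 1. Their shares are uncertain too. Gamma chain variable genes summed to 4.40 ± 0.962 TPM and Trdv genes to 19.4 ± 5.59 TPM.

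All tests below were chosen after the pattern was seen. Ighm stood far above the other B cell genes listed. Rearranged heavy chain transcripts are argued against, since reads on Ighv genes came to 0.252% of the Ighm reads, whereas Trbv reads came to 29.7% and 28.8% of Trbc1 and Trbc2 reads in the same libraries. Transcription of the heavy chain constant region without a variable segment may remain, as a hypothesis that no test here addressed. B cells as the source of most Ighm reads are likewise argued against, because light chain reads were also few. Igkc came to 3.52% of the Ighm TPM in library 1 and 2.98% in library 2. The 160 Igkv genes together held 29 and 28 reads, against 13162 and 13886 on Ighm. Whether some B cells were in the sample stays open. The median of the other 7 members of the B cell list was 0.186% of the Ighm TPM in library 1 and 0.224% in library 2. Cd79b, the highest, reached 5.36%, past the bound set for arguing against B cells in the sample. The design gives no second group, so no biological explanation resting on a comparison of groups was tested.

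Foxp3 reads were assigned mostly to transcripts without the long 3' untranslated part. Loss of 3' reads in all genes is argued against, since 846 and 853 genes of like coding share and coverage had a median whole-number to estimated count ratio of at most 0.387, against 0.748 and 0.770 for Foxp3. This holds only if the whole-number counts leave out reads outside coding exons, which is not given in the sources used here. The ratio placed Foxp3 at the 97.5th percentile or above of those genes, as an altered 3' untranslated part of the Foxp3 allele would give. It comes from the same reads as the transcript assignment, and any cause of few reads in the 3' part would raise it. The rank therefore does not single out an altered allele. The strain carries a Cre cassette at Foxp3, and a candidate explanation is that the cassette alters the 3' part of the transcript. The labels do not give the position of the cassette, a rank found after looking at this gene cannot exclude chance, and the reads themselves were not examined.

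The whole-number table levelled off at high expression. A uniform subsample of the reads is argued against, since the median count ratio of the top 1% of genes by reads per exonic base was at most 0.0466 of that in group 5 of 10. Keeping 1 read per start position and strand over coding exons may account for the ceiling: the count divided by that limit was 1.03 at the percentile that 1 gene in 1000 exceeds, against 32.5 and 30.4 for the estimated counts. Reads outside coding exons may have been left out, since across genes of low coverage the count ratio had a Spearman's rho of 0.534 or more with the coding share of exonic bases. Counts in that table would then understate abundant genes, and no biological explanation was tested.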
